A study of Mus musculus with 3 samples.

How the data were processed

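The series is a single-cell experiment on tumour-infiltrating T cells of C57BL/6 mice that carried subcutaneous B16-Ova or MC38-Ova tumours. Per the labels, cells were sorted on day 14 as TCRβ+ CD3+ CD90.2+ CD11b−, tagged with hashtag and antibody oligonucleotides, pooled and loaded in 1 10x Genomics 5′ capture. Hashtag 1 marks B16-Ova and hashtag 2 marks MC38-Ova. Antibody tags read PD-1, Tim-3 and biotin, and the anti-biotin tag reads biotinylated L-Pha, a plant lectin that binds β1,6-branched N-glycans. The number of mice behind each hashtag is not given. There is therefore 1 pool of cells per tumour and no replicate of either tumour, and no capture was made without the lectin. The T cell receptor library was not analysed, since the files at hand hold no table of it.

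Per the submitters' processing notes, the authors used Cell Ranger 3.1.0 with the mm10 genome, R 3.6.1 and Seurat 3.1.0, and the deposited matrix holds raw UMI counts per barcode. Per the file headers, the matrix was written by software version 3.0.2. The annotation release the authors counted with is not stated, and no header or label records whether barcodes or genes were filtered before deposit beyond the lowest total of 500 RNA UMIs seen in the table. The matrix holds 31053 genes, 2 hashtags and 3 antibody tags in 19912 barcodes. Gene coordinates printed are those of GENCODE vM21 on GRCm38 (mm10), matched by gene ID.

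Design, gene lists, marker lists, the rule for naming genes and the alternatives were fixed before the data were examined, except where a choice is said to be later. Hashtags were called with Seurat 5.3.0's HTODemux (centred log-ratio, positive quantile 0.99). The centred log-ratio was taken within each barcode over its hashtags, a choice made after the hashtag distributions and the calls of both forms were seen. Taken for each hashtag over all barcodes, it put the lowest count of hashtag 2 among both-hashtag barcodes at 443 UMIs, inside that hashtag's positive peak. In the form used, which sets no fixed count, the lowest was 172. For hashtag 1 these counts were 232 and 219. Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept, barcodes positive for both hashtags were dropped, and the highest Scrublet scores (scanpy 1.11.5, expected rate 0.25) were removed in each pool in the number of within-pool doublets that the both-hashtag barcodes imply. The Scrublet score separated both-hashtag barcodes from singlets with an area under the ROC curve of 0.752, so doublets remain among the kept cells.

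Kept cells were clustered on 2000 variable genes (without receptor segments, ribosomal, mitochondrial, sex-linked and proliferation-list genes), 30 principal components and 20 neighbours with Leiden resolution 1 (leidenalg 0.10.2). A cluster took a class name when at least 3 of the class's fixed markers stood at 20 CPM or more and 1.5-fold above the other cells, with a lead of 2 markers over the next class and no class having more markers among the 10 leading genes. A non-T name was refused above 300.0 CPM of Cd3e. These naming thresholds, and the measure by which leading genes were ranked, were set after the clusters were seen. Names carry the ending "-like" because they rest on transcripts alone.

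L-Pha, PD-1 and Tim-3 are given as UMIs per cell, with 95% bootstrap intervals of ratios of medians over cells (1000 resamples). Shares have exact Clopper-Pearson intervals. All of these intervals cover counting error only, since cells are not replicates. For L-Pha-high against L-Pha-low cells, UMIs of the top and bottom L-Pha quartile of each pool and class were summed, giving 4 sums per class. They were tested with edgeR 4.0.16 (TMM scaling, filterByExpr on the high and low groups, quasi-likelihood F-test) with the pool as a block and Benjamini-Hochberg adjustment over all genes tested, at 0.05. The block leaves 1 residual degree of freedom, so the spread is mostly borrowed across genes, and sums of cells from the same pools vary less than independent animals would. Total degrees of freedom were 13.8 in CD8-like, 36.1 in Treg-like and 7331 in CD4 conventional-like cells. In the last class the spread was wholly borrowed, so a gene's own spread between pools did not count. On counts simulated from these sums, 4-fold changes were recovered at 92.4% in CD8-like cells (9193 genes), 93.8% in Treg-like cells (8784 genes) and 97.0% in CD4 conventional-like cells (7111 genes). For 1.5-fold changes the recovery was 21.9%, 26.2% and 23.4%, and false calls made up 2.59%, 4.38% and 3.23% of calls. The simulation gave both pools the same fold and each gene the spread of the fitted trend. These rates therefore hold for that model only, and do not cover genes whose spread or fold differs between pools.

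MC38-Ova against B16-Ova expression is a ratio of CPM of the summed UMIs of a class, with an exact conditional 95% interval, for genes with at least 100 UMIs in the sums together. With 1 pool per tumour no test was made. The median of a gene list is given with its percentile among 10000 random lists of the same size matched on expression. DESeq2 1.42.0 was run as an alternative for the tested comparisons.

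The genes named are, for each tested comparison, the 12 largest rises and the 12 largest falls among called genes with the same direction in both pools and a mean of 20 CPM. For the tumour comparison they are the 12 highest and the 12 lowest by the interval bound nearest to no difference. Added to these are up to 4 leading members of each gene list and Mgat5, Pdcd1, Havcr2, Tcf7, Gzmb, Foxp3, Cd8a, Cd8b1, Cd4 and Xist. Of CD8-like genes, St6gal1, Ccl3, Ccl5, Klre1, Fcer1g, Xcl1, Tcrg-C2, Ighm, Itgax and Cdkn2a fall outside this rule and were chosen after their values were seen. Receptor segments, ribosomal proteins and unnamed gene models were counted but not named. The 20 gene lists are cytotoxic effector, exhaustion, naive and memory, proliferation, interferon response, early T cell receptor activation, dissociation stress, N-glycan branching, N-glycan precursor and oligosaccharyltransferase, hexosamine and UDP-GlcNAc, glycolysis, oxidative phosphorylation, ER secretory, galectin, tissue residency and adhesion, T cell surface glycoprotein, Treg, effector Treg, MHC class I presentation and cholesterol. A further 10 lists mark other cells (NK and NKT, γδ T, B, macrophage and monocyte, dendritic, neutrophil and mast, melanoma, colon carcinoma, stroma, erythroid). Lists overlap with each other in part. Aldoa and Atp5o, each present under several gene IDs, were left out of their lists.

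Alternatives were 2 other hashtag callers, a looser and a stricter cell filter, no Scrublet removal, Leiden resolutions 0.5 and 2, L-Pha per 100 hashtag UMIs or per 1000 RNA UMIs, other L-Pha splits (terciles, median, quartiles within RNA deciles, within clusters and by L-Pha per hashtag UMI), other scaling, filters, a fit without the block, DESeq2, and each pool alone. Chosen after the data were seen were the other form of the hashtag log-ratio, CD8-like cells without cluster 6, and quartiles within cluster and RNA tercile.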

Results

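Tumour-infiltrating T cells were profiled for RNA, for surface PD-1 and Tim-3, and for binding of the lectin L-Pha, read through an anti-biotin tag. L-Pha binds β1,6-branched N-glycans, the products of the Golgi enzyme encoded by Mgat5 (chromosome 1, 127205015 to 127488336, GRCm38). Cells came from B16-Ova melanoma and MC38-Ova colon carcinoma, both carrying ovalbumin, and were told apart by hashtag within 1 capture. Of the barcodes, 18429 passed the cell filter and 1483 did not. All of them held 169579110 RNA UMIs, with a median of 5942.5 RNA UMIs and 2001 genes per barcode, and a range of 500 to 111658 RNA UMIs. Of all barcodes, 32.9% (95% interval 32.3 to 33.6) carried the B16-Ova hashtag alone, 46.3% (45.6 to 47.0) the MC38-Ova hashtag alone, 13.6% both and 7.16% neither. After filtering, 5224 B16-Ova cells (41971273 RNA UMIs, median 5590.5) and 6675 MC38-Ova cells (45659976 RNA UMIs, median 5444) remained. Their median own-hashtag counts were 419 and 426 UMIs. Each tumour is 1 pool, so differences between tumours have no replicate check, and intervals cover counting error only. Because both pools shared 1 capture, free RNA was common to them.

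The cells formed 18 clusters, and 4 classes were compared: CD8-like, Treg-like, CD4 conventional-like and NK/NKT-like. The question was which infiltrating T cells each tumour held. CD8-like cells made up 18.2% of B16-Ova cells (953 cells, 17.2 to 19.3) and 24.0% of MC38-Ova cells (1600 cells, 23 to 25). They split differently: cluster 7, led by the cytotoxic genes Gzmf, Prf1 and Gzmc and by Spp1, held 582 B16-Ova and 179 MC38-Ova cells. Cluster 6, led by the chemokine genes Ccl4 and Ccl3 with Ifng, Lag3 and Il2, held 92 and 686, and cluster 4, led by Gzma, Ifitm1 and Cd8b1, held 279 and 735. Treg-like cells, led by Tnfrsf4, Areg, Foxp3, Ctla4 and Il2ra, made up 16.4% (855 cells) and 17.4% (1163 cells). CD4 conventional-like cells made up 16.2% (844 cells) and 13% (869 cells). Of them, cluster 10, led by Ifitm2, Il13, Tnfsf11, Il1r2 and Csf2, had 60 B16-Ova and 229 MC38-Ova cells. NK/NKT-like cells, led by Fcer1g, Klra7, Tyrobp and Xcl1 and sorted as TCRβ+ CD3+, made up 14.5% (758 cells) and 20.0% (1335 cells).

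In percentage points, MC38-Ova minus B16-Ova shares were 5.73 for CD8-like cells (3.63 to 7.81), 5.49 for NK/NKT-like cells (3.55 to 7.41), 1.06 for Treg-like cells (−0.878 to 2.98) and −3.14 for CD4 conventional-like cells (−4.96 to −1.32). The CD8-like and NK/NKT-like differences shrank to 2.26 and 0.198 with Leiden resolution 0.5. The Treg-like difference was −2.24 (−4.11 to −0.367) with resolution 2 and 11.4 (9.11 to 13.7) with the other form of the hashtag log-ratio, under which the CD4 conventional-like difference was −6.82 and the NK/NKT-like difference 3.18. The sort fixes the shares in part, and the other 11 clusters held 34.7% of B16-Ova cells (33.4 to 36) and 25.6% of MC38-Ova cells (24.5 to 26.7). Among them, cluster 5 carried the resting-cell genes Ccr7 and Dapl1 and held 471 and 314 cells, cluster 8 carried interferon-induced genes (170 and 353), and cluster 9 carried proliferation genes (230 and 133).

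**Figure D1:**
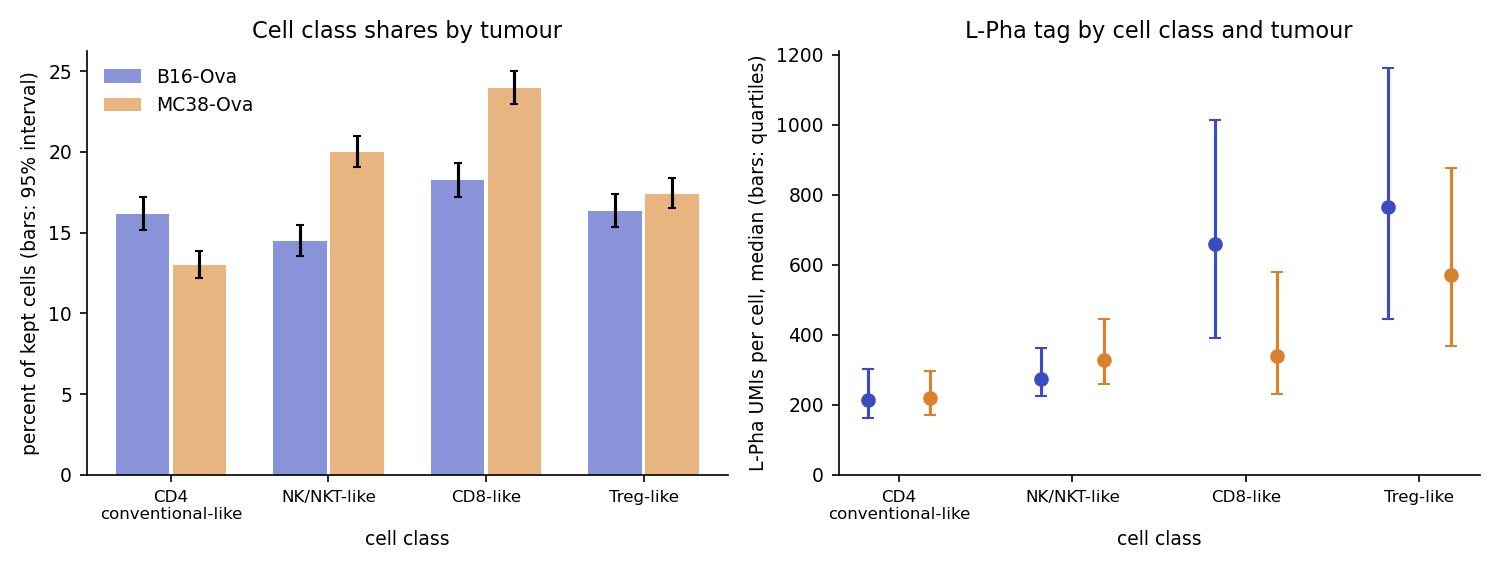
Left, percent of kept cells in each class by tumour, with 95% exact intervals (counting error only). Right, median L-Pha UMIs per cell with the quartiles of cells as bars, highest in Treg-like cells of both tumours (766 in B16-Ova, 571 in MC38-Ova).

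L-Pha binding was compared between classes to ask which infiltrating T cells carry branched N-glycans. By UMIs per cell, Treg-like cells bound the most, with medians of 766 L-Pha UMIs per cell in B16-Ova (quartiles 446 to 1161) and 571 in MC38-Ova (368 to 875). CD8-like cells had 658 (392 to 1012) and 340.5 (229.75 to 580.5). NK/NKT-like cells had 274 and 329, and CD4 conventional-like cells the least, with 213 (162 to 303) and 220.0 (172 to 296). Barcodes with neither hashtag, with a median of 2889 RNA UMIs, had a median of 162 L-Pha UMIs. These barcodes came from the same capture and held few hashtag UMIs (medians 87 and 50), so 162 is not a level without the lectin. Of the 4 classes, CD4 conventional-like cells had the medians nearest to it. Without a capture lacking the lectin, the ratios to these cells were not corrected for background. Relative to CD4 conventional-like cells, the Treg-like median was 3.6-fold (3.26 to 3.88) and 2.60-fold (2.47 to 2.73), the CD8-like median 3.09-fold (2.86 to 3.34) and 1.55-fold (1.47 to 1.64), and the NK/NKT-like median 1.29-fold (1.21 to 1.36) and 1.5-fold (1.43 to 1.56).

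In B16-Ova the order of Treg-like and CD8-like cells turned per 100 hashtag UMIs (2.07-fold and 2.36-fold) and with Leiden resolution 0.5 (2.80-fold and 3.12-fold). In MC38-Ova the order of CD8-like and NK/NKT-like cells turned with hashtags called by the mixture (1.53-fold and 1.56-fold) and per 1000 RNA UMIs (0.877-fold and 1.07-fold). CD8-like and Treg-like cells also held more RNA. Per 1000 RNA UMIs the Treg-like ratio was 1.85 and 1.51, while the CD8-like ratio was 1.19 in B16-Ova and 0.877 in MC38-Ova, where the direction turned. Within CD8-like cells, L-Pha was highest in the Gzmf- and Prf1-rich cluster 7 (medians 837 and 598), then in cluster 6 (529.5 and 405), and lowest in cluster 4 (356 and 260.0).

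PD-1 and Tim-3 are surface receptors that rise on chronically stimulated T cells, and CD8-like cells were divided into quartiles of each to see how branched N-glycans go with them. From the lowest to the highest PD-1 quartile, median L-Pha went from 387.5 to 1133.5 UMIs in B16-Ova and from 258 to 520.0 in MC38-Ova, ratios of 2.93 (2.52 to 3.35) and 2.02 (1.83 to 2.26). From the lowest to the highest Tim-3 quartile it went from 412 to 1024.5 and from 261.5 to 492, ratios of 2.49 (2.13 to 2.86) and 1.88 (1.66 to 2.07). Transcripts also differed between the lowest and highest quartiles. Pdcd1 went from 254 to 587 CPM in B16-Ova and from 279 to 626 CPM in MC38-Ova across PD-1 quartiles. Havcr2, which encodes Tim-3, went from 109 to 214 CPM and from 111 to 293 CPM across Tim-3 quartiles. In B16-Ova, however, Pdcd1 stood at 565, 620 and 587 CPM in PD-1 quartiles 2, 3 and 4. Median RNA went from 7837 to 15674 UMIs over those quartiles.

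Across cells, Spearman's rho between L-Pha and PD-1 was 0.543 in B16-Ova and 0.396 in MC38-Ova, and between L-Pha and Tim-3 0.496 and 0.347. Cells are not independent replicates, and rho was 0.617 and 0.507 between L-Pha and total RNA and 0.496 in both tumours between L-Pha and the own hashtag. With quartiles taken within deciles of RNA UMIs, the PD-1 ratios were 1.55 and 1.53 and the Tim-3 ratios 1.55 and 1.32. Per 1000 RNA UMIs, the PD-1 ratios were 1.09 (0.978 to 1.21) and 1.28 (1.12 to 1.42). The Tim-3 ratios were then 1.21 (1.11 to 1.35) and 1.06 (0.940 to 1.21). Per 100 hashtag UMIs, they were 1.59 and 1.16 for PD-1 and 1.60 and 1.11 for Tim-3. The association was not particular to CD8-like cells. Within RNA deciles, mean rho of L-Pha with PD-1 was 0.335 and 0.294 in CD8-like and 0.323 and 0.221 in NK/NKT-like cells. With Tim-3 it was 0.347 and 0.209 in CD8-like and 0.324 and 0.259 in NK/NKT-like cells. Havcr2 stayed at 15.5 and 12.3 CPM in the highest Tim-3 quartile of NK/NKT-like cells.

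**Figure D2:**
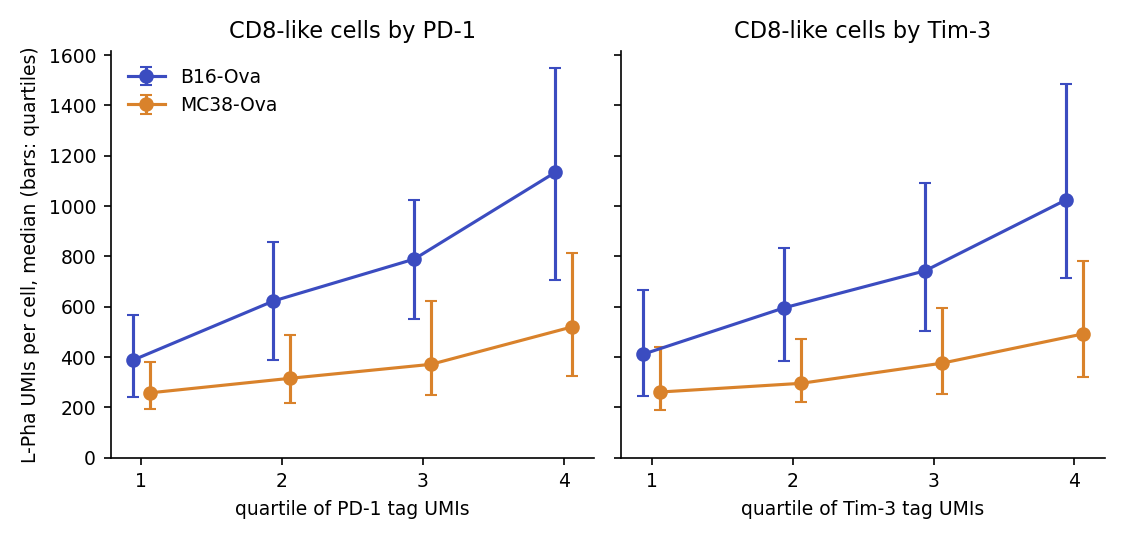
Median L-Pha UMIs per CD8-like cell by quartile of PD-1 (left) and Tim-3 (right) tag UMIs, with the quartiles of cells as bars. Medians rise from the lowest to the highest quartile in both tumours, from 387.5 to 1133.5 for PD-1 in B16-Ova.

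L-Pha-high CD8-like cells were set against L-Pha-low ones to ask which programmes go with branched N-glycans. Some genes of the exhaustion, proliferation, glycolysis and ER secretory lists rose in L-Pha-high cells. Some genes of the naive and memory, tissue residency and adhesion, and dissociation stress lists fell. Spp1, which encodes osteopontin, rose by 4.57 ± 0.32 on the log2 scale (± SE), Gzmc by 3.54 ± 0.61, Gzmf by 3.56 ± 0.59 and Prf1 by 1.98 ± 0.13. Tcf7, a transcription factor of memory-like T cells, fell by 1.61 ± 0.18, and S1pr1, the receptor for leaving tissue, fell by 2.17 ± 0.20. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 698 of 9357 genes passed 0.05, 339 higher and 359 lower in L-Pha-high cells. Of all genes tested, 67.2% had the same direction in both pools.

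Among genes with a mean of 20 CPM or more, the other largest rises were in Serpine2 (log2 4.06), Ccl9 (3.29), Serpinb9b (2.69), Myo10 (2.64), Gldc (2.42), Areg (2.24), Mt2 (2.23), Ccna2 (2.18) and Nrgn (2.16). Gzmf, Gzmc and Serpinb9b rose far more in B16-Ova (6.18, 6.64 and 7.88) than in MC38-Ova (1.72, 1.72 and 1.27), and the difference between pools was not tested. The largest falls at that level were in Gzmm (−2.23), S1pr1, Cmah (−1.93), Ifitm1 (−1.83), Klf3 (−1.77), Tespa1 (−1.73), Mylip (−1.64), Ripor2 (−1.63), Tcf7, Cd7 (−1.61), Cd69 (−1.59) and Lcn4 (−1.57). Cmah encodes the enzyme that makes the sialic acid Neu5Gc.

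In the exhaustion list, 11 of 18 genes rose and 0 fell (13 and 1 adjusted over the list alone). Tnfrsf9 (1.17), Rgs16 (0.96), Tox (0.90) and Entpd1 (0.86) were among them. Pdcd1 rose by 0.68 ± 0.11 (adjusted p 0.0028 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and Havcr2 by 0.64 ± 0.14 (adjusted p 0.0143). Of 20 cytotoxic effector genes 5 rose and 2 fell (7 and 6 adjusted over the list alone), where Gzmb rose by 0.85 ± 0.10 and the chemokine gene Ccl3 by 0.57, while Tnf (−0.92) and Ccl5 (−0.77) fell. The median of that list was −0.19 in B16-Ova and 0.39 in MC38-Ova, so the pools opposed each other. Of 30 proliferation genes 22 rose and 0 fell (29 and 0 adjusted over the list alone), with Ccnb2 at 1.75 and Birc5 at 1.64. Of 17 glycolysis genes 8 rose (11 adjusted over the list alone), with the lactate exporter Slc16a3 at 1.06 and Tpi1 at 0.96. Of 26 ER secretory genes 9 rose (13 up and 1 down adjusted over the list alone), with the chaperone Hsp90b1 at 0.70.

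Fewer rises came from the Treg list (3 of 12, 6 adjusted over the list alone), with Tnfrsf9, Ikzf2 (1.07) and Tnfrsf4 (0.86), and from the cholesterol list (2 of 15, 4 adjusted over the list alone), with Idi1 (0.89) and Cyp51 (0.80). The cholesterol median was 0.96 in B16-Ova but 0.08 in MC38-Ova. The N-glycan precursor and oligosaccharyltransferase list had 2 rises among 33 genes (2 adjusted over the list alone), Prkcsh (0.61) and Rpn1 (0.52), and the hexosamine list 1 among 10 (1 adjusted over the list alone), Gnpnat1 (0.62). The effector Treg list had 10 rises and 4 falls among 28 genes (12 and 6 adjusted over the list alone).

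In the naive and memory list 8 of 11 genes fell and 0 rose (9 and 0 adjusted over the list alone), Klf2 at −1.56 among them. In the tissue residency and adhesion list 11 of 20 fell and 0 rose (13 and 0 adjusted over the list alone). That list joins genes such as Cd69 with S1pr1, the receptor for leaving tissue, and with Klf2 and Klf3. These fell alike, so the count does not by itself mean less residency. In the dissociation stress list 9 of 16 fell and 0 rose (10 and 1 adjusted over the list alone), with the immediate early gene Fos at −1.44. The early T cell receptor activation list had 3 rises and 7 falls among 20 genes (3 and 8 adjusted over the list alone), with the transcription factor gene Irf8 at 1.11, and the interferon list 1 fall among 16 (8 adjusted over the list alone), Ifit3 (−1.19). The interferon median was −1.20 in B16-Ova but −0.03 in MC38-Ova. In the N-glycan branching list 3 of 20 genes fell and 0 rose (6 and 0 adjusted over the list alone), namely St6gal1 (−2.29 ± 0.33, at 13.4 CPM), which adds α2,6-linked sialic acid to N-glycans, the sialyltransferase gene St3gal6 (−0.84) and B3gnt2 (−0.81), which extends N-acetyllactosamine chains. Mgat5 itself, at 12.5 CPM, did not pass the test (−0.49 ± 0.31, adjusted p 0.369 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

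In edgeR's quasi-likelihood test, which called 698 genes and put 2103 below an unadjusted p of 0.05, no gene was called among 24 oxidative phosphorylation genes (3 up adjusted over the list alone), 5 galectin genes (1 up and 1 down adjusted over the list alone) and 13 MHC class I genes (0 adjusted over the list alone). Of 26 T cell surface glycoprotein genes, the costimulatory receptor gene Cd28 fell (−0.65, 1 adjusted over the list alone). Among markers of other cells, Fcer1g (2.00) and Klre1 (1.42) rose and Xcl1 (−0.44) fell of 6 NK and NKT genes (3 and 1 adjusted over the list alone), and Tcrg-C2 (3.25) rose as the only γδ T gene tested (1 adjusted over the list alone). Ighm (−0.84) fell of 3 B cell genes (1 up and 2 down adjusted over the list alone), Itgax (−1.58) of 5 dendritic genes (1 and 1 adjusted over the list alone), and Cdkn2a (1.77) rose of 5 melanoma genes (1 adjusted over the list alone). The macrophage, colon carcinoma and stroma lists had 0 calls among 5, 2 and 1 genes tested, and no neutrophil and mast or erythroid gene was tested. Cd8a (0.20), Cd8b1 (−0.40), Foxp3 (0.79), Cd4 (−0.22) and Xist (−0.32) did not pass.

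The L-Pha groups differed in cluster and depth. Cluster 7 held 88.7% of L-Pha-high and 19.7% of L-Pha-low cells in B16-Ova. In MC38-Ova, cluster 6 held 54.3% of L-Pha-high cells and cluster 4 held 73.8% of L-Pha-low cells. Median RNA was 15649 against 5116 UMIs in B16-Ova and 10202 against 4813.5 in MC38-Ova. Within clusters, Havcr2 (−0.33), Entpd1 (−0.25) and Rgs16 (−0.10) of the exhaustion list turned. With L-Pha quartiles taken within clusters 101 genes passed, within RNA deciles 93, and within both cluster and RNA tercile 43. Within RNA deciles Ccl3 stood at −1.06, Ccl9 at −0.50, Gzmc at −0.17, Gzmb at −0.16 and Tpi1 at −0.11, and of the glycosylation genes Rpn1 at −0.19 and Gnpnat1 at −0.28, while within cluster and RNA tercile Gzmf stood at −0.48, Tcf7 at 0.13, Rpn1 at −0.14 and Gnpnat1 at −0.28. Within clusters Gnpnat1 stood at −0.0168.

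**Figure D3:**
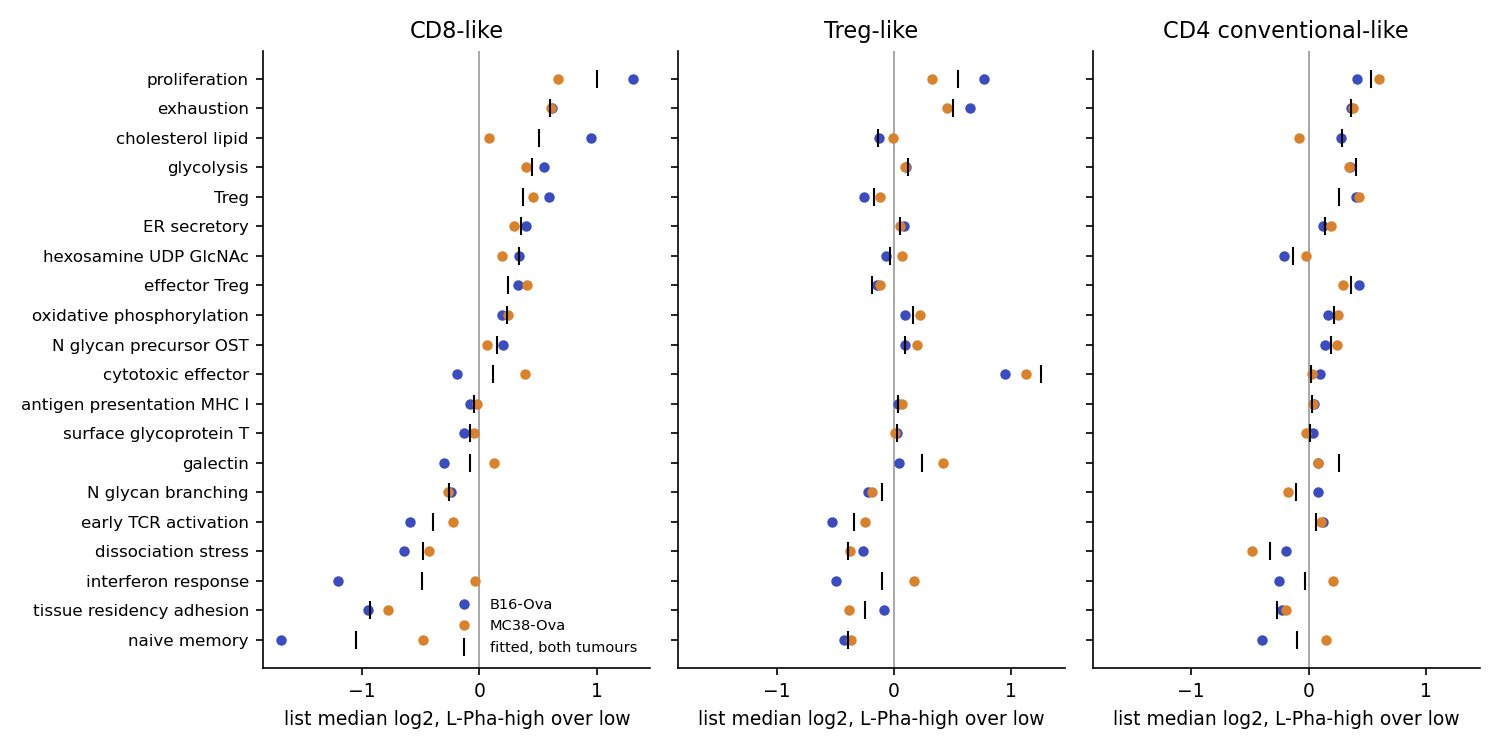
Median log2 ratio of each gene list, L-Pha-high over L-Pha-low cells, in 3 classes, with points for each tumour and a tick for the fitted value. In CD8-like cells the proliferation list (1.00) lies highest and the naive and memory list (−1.05) lowest.

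In Treg-like cells, some genes of the cytotoxic effector, exhaustion and proliferation lists rose in L-Pha-high cells, and some of the dissociation stress list fell. Nkg7 rose by 1.62 ± 0.09, Cd8a by 1.58 ± 0.16, Cd8b1 by 1.39 ± 0.13, Prf1 by 1.55 ± 0.21 and the DNA synthesis gene Rrm2 by 2.18 ± 0.25. Most Cd8a and Cd8b1 UMIs of L-Pha-high cells lay in a minority of them. In B16-Ova 65 of 213 cells held 94.7%, and in MC38-Ova 115 of 290 held 96.7%. St6gal1 fell here too, by 2.35 ± 0.26, and Foxp3 fell by 0.33 ± 0.10. Of 8964 genes, 507 passed edgeR's quasi-likelihood test, 231 higher and 276 lower. With terciles 219 passed, within RNA deciles 281 and with DESeq2 58. Of all genes tested, 60.8% had the same direction in both pools. Median RNA was 12103 UMIs in L-Pha-high against 4969 in L-Pha-low cells of B16-Ova, and 10233 against 3759 in MC38-Ova.

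The other leading rises among genes at 20 CPM or more were Tk1 (2.14), Pclaf (1.98), Mt3 (1.95), Ccl3 (1.77), Mcm2 (1.68), Tmem163 (1.63), Gzmk (1.60) and Mcm5 (1.60). The leading falls, after St6gal1, were Cd83 (−1.94), Cxcl10 (−1.84), Ly6c1 (−1.76), Rflnb (−1.72), Il6ra (−1.57), Il1rl1 (−1.41), Tnfrsf25 (−1.40), Cxcl2 (−1.29), Ecm1 (−1.26) and Trat1 (−1.26). Of 17 cytotoxic effector genes 12 rose (14 adjusted over the list alone), of 17 exhaustion genes 9 rose (11 up and 1 down adjusted over the list alone), with Cxcr6 at 1.41, Ccl4 at 1.36 and Pdcd1 at 0.87, and of 30 proliferation genes 13 rose (19 adjusted over the list alone). Klrg1 rose by 1.19 and the galectin gene Lgals1 by 0.74. Of 16 dissociation stress genes 9 fell and 1 rose (10 and 2 adjusted over the list alone), with Fos at −1.21. Egr1 (−0.998), Nt5e (−1.02) and Klf2 (−0.92) fell too. In the effector Treg list 3 genes rose and 7 fell among 28 (6 and 13 adjusted over the list alone). In the N-glycan branching list 3 of 20 genes fell and 0 rose (3 and 0 adjusted over the list alone): St6gal1, Man1a (−0.68) and B3gnt2 (−0.67).

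Mgat5 (−0.16 ± 0.34), Havcr2 (0.49), Gzmb (0.27), Tcf7 (0.09), Cd4 (−0.02) and Xist (−0.31) did not pass in Treg-like cells. With L-Pha taken per hashtag UMI, Cd8a (−0.83), Cd8b1 (−1.03), Gzmk (−0.26), Ccl3 and Ccl4 turned. Within RNA deciles Foxp3 turned to 0.0874 and the replication genes turned, Pclaf to −0.72 and Mcm2 to −0.53. St6gal1 stayed lower in each split tried.

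In CD4 conventional-like cells with high L-Pha, the cytokine genes Il13, Il5 and Csf2 had the largest rises among genes at 20 CPM or more. Il13 rose by 5.85 ± 0.40, Il5 by 4.73 ± 0.48 and Csf2 by 3.51 ± 0.28, followed by Dusp14 (3.27), Igfbp7 (3.06), Cd83 (2.78), Ebi3 (2.57), Il1r2 (2.23), Ube2c (2.22), Il2 (1.99), Penk (1.97) and Cd81 (1.93). Also higher were Ccr7 (1.69), Cd8b1 (1.56), Areg (1.32), Ifng (1.25), the checkpoint gene Lag3 (1.11) and Il2ra (1.11). Falls were smaller: Rflnb (−1.23), Sidt1 (−1.19), Dtx1 (−1.18), Rhob (−1.14), Il6ra (−1.09), Klf2 (−0.95), Il7r (−0.90), S1pr1 (−0.85) and Tcf7 (−0.50). Of 7331 genes, 354 passed edgeR's quasi-likelihood test, 199 higher and 155 lower.

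Of 17 glycolysis genes 7 rose (7 adjusted over the list alone), of 27 effector Treg genes 10 rose and 1 fell (14 and 4 adjusted over the list alone), and of 16 exhaustion genes 5 rose (9 adjusted over the list alone). In the N-glycan branching list, edgeR's test called 0 of 18 genes (0 adjusted over the list alone). Mgat5 (0.37 ± 0.40), Pdcd1 (0.14), Havcr2 (0.63), Gzmb (−0.24), Foxp3 (0.87), Cd8a (0.64), Cd4 (−0.15) and Xist (−0.17) did not pass. The cytokine cluster 10 held 41.0% of L-Pha-high and 14.7% of L-Pha-low cells in MC38-Ova, and 14.2% and 0.474% in B16-Ova. Within clusters, 66 genes passed and Il13 stood at −0.22, while with L-Pha per hashtag UMI 13 genes passed and Il13 stood at −1.40, Csf2 at −0.38 and Ifng at −1.57. Il2 turned within RNA deciles (−1.30), within clusters (−1.58) and within both cluster and RNA tercile (−2.07), and within RNA deciles Il13 (−0.45), Igfbp7 (−0.28) and Ube2c (−0.70) turned too.

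Calls overlapped between classes. CD8-like and Treg-like cells shared 83 rises and 97 falls, against 7.97 and 10.4 for independent lists, with 9 genes called in opposite directions. CD8-like and CD4 conventional-like cells shared 57 and 81 (6.51 and 7.01 for independent lists), and Treg-like and CD4 conventional-like cells 35 and 56 (5.16 and 5.46). The sums of the classes share no cells, but L-Pha-high cells had more RNA in each class.

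Between tumours, CD8-like cells of MC38-Ova had higher levels of Il2, of interferon-induced genes and of the naive and memory list, and lower levels of Spp1, Tox, the proliferation list and the cholesterol list, though not in each cluster. The question was how the same antigen-bearing design differs between tumours. Il2 (chromosome 3, 37120523 to 37125959) stood at 186 against 6.33 CPM, a ratio of 29.4 (23.1 to 38.1). Ifitm1 stood at 642 against 36 CPM (17.8-fold, 16.1 to 19.8). Spp1 (chromosome 5, 104435118 to 104441050) stood at 12.8 against 302 CPM, a ratio of 0.0424 (0.0361 to 0.0496). Tox, a transcription factor of exhausted T cells, had a ratio of 0.267 (0.243 to 0.293).

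Other high ratios were those of Hrh4 (27.5), Ifitm2 (14.4), Ccr10 (12.7), Ifi204 (8.25), Tnfsf14 (8.24), Ifitm3 (6.82) and Lmna (5.55). Other low ratios were those of Epdr1 (0.0137), Slc16a11 (0.0193), Dscam (0.0275), Filip1 (0.0786), Ccdc184 (0.0809), Gzmf (0.200) and Gzmd (0.234). Haemoglobin genes were also among the lowest, but 1 cell held 1795 of the 1807 haemoglobin UMIs of B16-Ova cluster 7. Tnf (4.62), Ccl4 (4.09), the galectin gene Lgals3 (3.04), S1pr1 (2.89), Cd69 (2.64) and Gzmb (1.93) were higher in MC38-Ova, and Tk1 (0.410), Idi1 (0.281), Cyp51 (0.279) and the heat-shock gene Hspa1a (0.248) were lower. Mgat5 had a ratio of 1.07 (0.840 to 1.38), Pdcd1 0.880 (0.849 to 0.913), Havcr2 1.14 (1.08 to 1.22) and Tcf7 1.62 (1.44 to 1.84). Among lineage genes, Cd8a stood at 1.07 (1.05 to 1.10), Cd8b1 at 1.21 (1.19 to 1.24), Foxp3 at 0.939 (0.768 to 1.15) and Cd4 at 1.44 (1.18 to 1.76), and the X-linked Xist at 1.07 (1.02 to 1.12).

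Among lists, the interferon median was log2 1.55 (15 of 16 genes with an interval above 1), with Ifit3 at 4.34-fold and Ifit1 at 3.90-fold. The naive and memory median was 0.70, early T cell receptor activation 0.64, galectin 0.60, tissue residency and adhesion 0.51 and glycolysis 0.37. The tissue residency and adhesion list holds both S1pr1 and Cd69, each higher in MC38-Ova, so its median has no single reading. The proliferation median was −0.81 (30 of 30 genes with an interval below 1, percentile 0), cholesterol −1.12 (13 of 15) and exhaustion −0.25 (11 of 18, percentile 0.03), while the cytotoxic effector median was 0.00.

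Different clusters held most CD8-like cells of each tumour. From B16-Ova to MC38-Ova, Il2 went from 44.4 to 328 CPM in cluster 6, from 5.01 to 7.45 in cluster 4 and from 1.02 to 0.702 in cluster 7. Ifitm1 went from 67.9 to 724 CPM in cluster 6, from 160 to 690 in cluster 4 and from 6.13 to 76.6 in cluster 7. Spp1 went from 406 to 42.1 CPM in cluster 7, but from 7.83 to 12.9 in cluster 6 and from 3.13 to 3.03 in cluster 4. Of the proliferation list, Tk1 went from 70.5 to 50.6 CPM in cluster 7 and from 43.5 to 21.2 in cluster 6, but from 10.0 to 19.8 in cluster 4, where the other 3 leading members of that list were higher in MC38-Ova too. Gzmf went from 729 to 334 CPM in cluster 7, but from 0 to 125.6 CPM in cluster 6 and from 0.626 to 2.56 CPM in cluster 4, and Gzmd from 0.870 to 37.3 CPM in cluster 6. Pdcd1 went from 627 to 588 CPM in cluster 7, but from 170 to 233 in cluster 4 and from 448 to 593 in cluster 6. Without cluster 6, Cd8a (0.783), Gzmb (0.821), Ccl4 (0.657) and Havcr2 (0.447) were lower in MC38-Ova and the glycolysis median was −0.15. With clusters weighted equally, Pdcd1 (1.14), Tcf7 (0.734) and the naive and memory median (−0.12) turned, and the proliferation median was −0.20.

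Treg-like cells of MC38-Ova also had higher interferon-induced genes and lower cholesterol synthesis genes, together with higher Gzmb and Il2ra. They formed 1 cluster with those of B16-Ova, but at Leiden resolution 2 a Treg-like cluster of 653 B16-Ova and 109 MC38-Ova cells (Gzmb at 1509 CPM) parted from one of 42 and 691 (Gzmb at 5719.5 CPM). Gzmb stood at 4873 against 1295 CPM (3.76-fold, 3.68 to 3.85) and Il2ra, the IL-2 receptor gene, at 705 against 313 CPM (2.25-fold, 2.15 to 2.36). The highest ratios were those of Ifitm1 (13, 10.7 to 16), Ifi44 (11), Tctex1d1 (8.46), Gpld1 (8.21), Ly6c1 (7.72), Ifitm3 (7.58), Usp18 (5.57) and Ecm1 (4.03), and of haemoglobin genes, where 1 cell held 2366 of 2399 UMIs. The lowest were those of Fcrl6 (0.124), Hspa1a (0.184), Penk (0.206), Serpina3f (0.210), Ramp1 (0.214), Tmem158 (0.225) and Cd74 (0.269).

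The interferon median in Treg-like cells was 1.56 (17 of 18 genes with an interval above 1), with Ifit1 at 4.02-fold and Ifit3 at 3.94-fold. The galectin median was 0.69, with Lgals3 at 3.34-fold, the naive and memory median 0.68, although Ccr7 had a ratio of 0.384, the glycolysis median 0.32 and the cytotoxic effector median 0.17. The cholesterol median was −1.23 (13 of 14 genes with an interval below 1), with Cyp51 at 0.332, Hmgcs1 at 0.342 and Idi1 at 0.349, the proliferation median −0.66 (25 of 30) and the exhaustion median −0.30 (13 of 17), with Tox at 0.465. Foxp3 had a ratio of 1.11 (1.05 to 1.16), Mgat5 0.834 (0.620 to 1.12), Pdcd1 0.673 (0.625 to 0.724), Havcr2 0.753 (0.673 to 0.843) and Tcf7 1.33 (1.10 to 1.60).

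**Figure D4:**
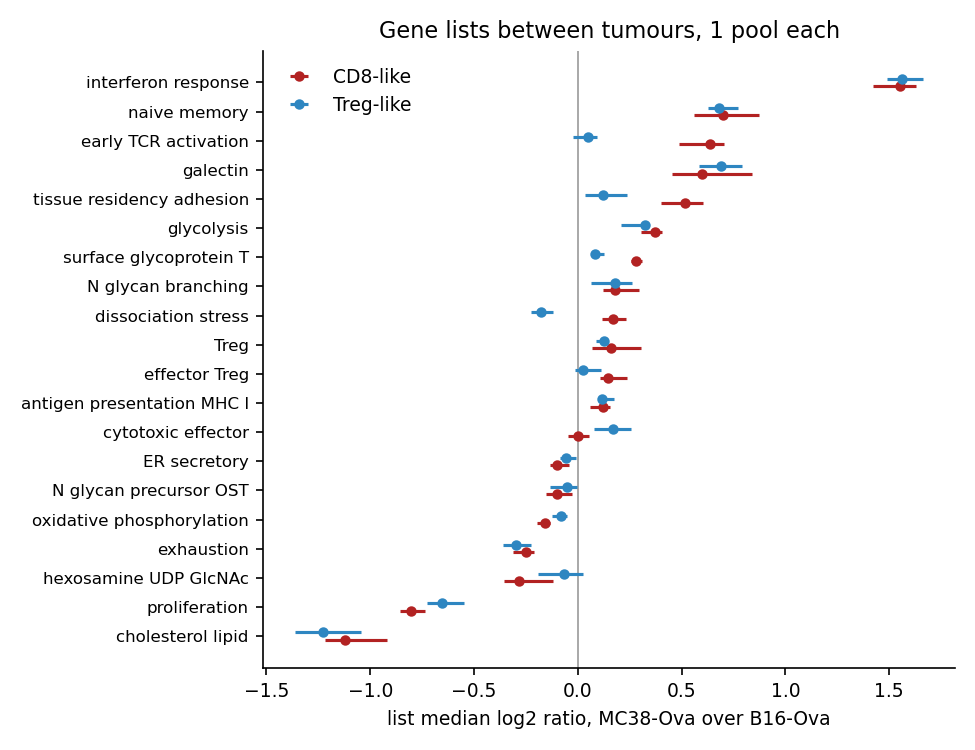
Median log2 ratio of each gene list, MC38-Ova over B16-Ova, in CD8-like and Treg-like cells, with 95% intervals for counting error. The interferon list lies highest (1.55 and 1.56) and the cholesterol list lowest (−1.12 and −1.23), with 1 pool per tumour and no test.

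At the surface, CD8-like cells of MC38-Ova bound less L-Pha than those of B16-Ova, with a ratio of medians of 0.517 (0.480 to 0.559), and so did Treg-like cells, with 0.745 (0.690 to 0.814). For CD4 conventional-like cells the ratio was 1.03 (0.972 to 1.10) and for NK/NKT-like cells 1.20 (1.15 to 1.24), which turned to 0.969 (0.938 to 0.993) per 100 hashtag UMIs. PD-1 was lower in MC38-Ova on CD8-like cells (0.875, 0.840 to 0.913) and on Treg-like cells (0.850, 0.810 to 0.900). Tim-3 ratios were 0.957 (0.917 to 1.00) and 0.913 (0.870 to 0.955). Both tags were counted in few UMIs. CD8-like medians in B16-Ova and MC38-Ova were 24 and 21 for PD-1 and 23 and 22 for Tim-3. Treg-like medians were 20 and 17 for PD-1 and 23 and 21 for Tim-3. NK/NKT-like cells had 14 for PD-1 and 18 for Tim-3 in both tumours, so these ratios rest on small differences in count. Per 1000 RNA UMIs the CD8-like ratio was 0.739 for L-Pha but 1.16 for PD-1 and 1.19 for Tim-3 (1.12 to 1.28). The ratio of median RNA UMIs was 0.829. Within cluster 7 the L-Pha medians were 837 in B16-Ova and 598 in MC38-Ova, where median RNA was 11613.5 and 7192 UMIs, a larger drop. Within cluster 4 they were 356 and 260.0, with 5187 and 5286 RNA UMIs.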

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

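The tests with genes chosen from middle L-Pha cells, of doublets with cluster 7 and of the CD8-like differences were chosen only after the result was seen.

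Oas1a, Ifitm1 and Ly6c1 went with L-Pha in opposite directions in the 2 tumours, and these differences between tumours were not tested. Oas1a, which encodes an interferon-induced antiviral enzyme, was lower in L-Pha-high CD8-like cells of B16-Ova (log2 −1.38, fold 0.385, interval 0.222 to 0.632, 31 UMIs in low and 33 in high cells) and higher in those of MC38-Ova (1.17, fold 2.25, 1.59 to 3.11, 45 and 219 UMIs). Ifitm1 was lower in L-Pha-high Treg-like cells of B16-Ova (−1.74, fold 0.3, 0.121 to 0.618, 17 and 12 UMIs) and higher in those of MC38-Ova (1.12, fold 2.17, 1.73 to 2.67, 100 and 598 UMIs). In CD4 conventional-like cells Ifitm1 went the same ways, −3.74 in B16-Ova (fold 0.0746, 0.0166 to 0.179, 36 and 4 UMIs) and 1.33 in MC38-Ova (fold 2.52, 1.97 to 3.12, 92 and 451 UMIs). Ly6c1 was higher in L-Pha-high CD4 conventional-like cells of B16-Ova (2.10, fold 4.28, 1.58 to 17.5, 4 and 31 UMIs) and lower in those of MC38-Ova (−1.72, fold 0.303, 0.145 to 0.550, 28 and 16 UMIs). The intervals cover counting error only. Although the pools opposed each other, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called Ifitm1 in Treg-like (adjusted p 0.0405) and CD4 conventional-like cells (0.0139). A call therefore does not by itself mean that both pools go the same way. Of called genes, 99.6% in CD8-like, 99.0% in Treg-like and 98.6% in CD4 conventional-like cells had the same direction in both pools.

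Signals also lay in barcodes and clusters outside the comparisons. Median L-Pha was 162 UMIs in barcodes with neither hashtag and 750.5 in barcodes with both. Cluster 13, led by Prf1, Penk, Rgs16, Lag3 and Areg and left without a class name, had a median L-Pha of 1888 UMIs. The 24 melanoma-like cells with the MC38-Ova hashtag held the melanocyte gene Pmel at 2825 CPM, against 6534 CPM in the 30 melanoma-like cells with the B16-Ova hashtag.

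CD8 transcripts rose in L-Pha-high Treg-like cells: of genes abundant in CD8-like cells and low in L-Pha-low Treg-like cells, a choice that favours a rise, 25 of 31 were higher in L-Pha-high Treg-like cells of B16-Ova (80.6%) and 30 of 32 in MC38-Ova (93.8%). With such genes chosen from Treg-like cells of middle L-Pha, 17 of 22 (77.3%) and 20 of 21 (95.2%) were higher, against 53.3% and 47.2% of other genes at that level, so doublets with CD8-like cells cannot be told apart, as B16-Ova lies between the bounds set. Cells with at least 2 UMIs of Cd8a and Cd8b1 together were 65 of 213 L-Pha-high cells in B16-Ova and 115 of 290 in MC38-Ova. They held 94.7% and 96.7% of these UMIs. Their median RNA was 17882 and 14666 UMIs, against 12103 and 10233 in all L-Pha-high cells. More RNA makes 2 UMIs likelier, but the 213 cells held 847 such UMIs and the 290 cells 1547. That nearly all lay in a minority argues against depth alone for how they were spread over cells. It does not show why these UMIs rose with L-Pha, nor whether the cells were doublets. Doublets with cluster 7 cells taken at random were argued against, since Gzmf reached 5.64% of the mean level they need (upper bound 12.3%), but doublets with its cells of low Gzmf stay open, as at Leiden resolution 2 Gzmf stood at 2403 CPM in 123 CD8-like cells and at 74.99 CPM in 481 others. RNA depth cannot be told apart, as within RNA deciles Cd8a shrank from 1.58 ± 0.16 to 0.75 ± 0.22 and Cd8b1 from 1.39 ± 0.13 to 0.27 ± 0.20 (mean 0.51), and neither passed 0.05 with the smaller change and wider error. Per hashtag UMI both turned (−0.83 and −1.03), own-hashtag medians being 1035 against 392.5 in high and low cells of B16-Ova and 840.5 against 405 in MC38-Ova, and no biological explanation was tested.

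For the L-Pha-high differences in CD8-like cells, RNA depth and cluster composition were tested by how many of the 698 called genes were still called in the same direction once each was matched. With RNA deciles 43 were, and within clusters 85. That argues against RNA depth alone, or membership of these clusters alone, as the whole cause for those genes. Each split left the other factor free and drew on the same cells and pools as the main comparison. Finer groups of cells within a cluster were not matched. Within cluster and RNA tercile 23 were still called, but median RNA differed by more than a bound set after these medians were seen. It was 8815.5 against 8276 UMIs in B16-Ova and 7536 against 6905.5 in MC38-Ova, so cluster and depth together cannot be told apart. The median change of the called genes shrank from 0.90 to 0.23 with RNA deciles, from 0.91 to 0.32 within clusters and from 0.90 to 0.11 with both, and the genes no longer called stay open. No biological explanation was tested.

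Cluster 13 held 132 B16-Ova cells and 1 MC38-Ova cell, against 246 and 18 singlets before Scrublet removal. Its cells had a median of 20057 RNA UMIs and of 0.389 for the Scrublet score, and held Cd8a at 611 CPM beside Foxp3 at 177 CPM. Their medians of hashtag 1 and L-Pha were 1323 and 1888 UMIs. In B16-Ova, cluster 7 and Treg-like cells had medians of 482 and 561 for hashtag 1 and 837 and 766 for L-Pha. Their RNA medians were 11613.5 and 6756 UMIs, so each value lay below that of cluster 13. Random droplet doublets, paired irrespective of cell type, would place 676 both-hashtag barcodes there, and 109 were found, 16.1% of that number and between the bounds set, so such doublets cannot be told apart. The MC38-Ova count restates the pattern and decides nothing about doublets. Doublets of cell types that B16-Ova held more of, and a difference between the tumours, stay open and untested.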

How the results depend on the processing

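The form of the hashtag log-ratio, leaving out cluster 6 and splitting within cluster and RNA tercile were alternatives chosen only after the results were seen. Except where named below, results kept their direction. Named genes of the L-Pha comparisons kept their direction but no longer passed 0.05 in 17 cases with terciles, 31 at the median, 55 within RNA deciles, 40 within clusters, 58 within cluster and RNA tercile, 38 with L-Pha per hashtag UMI, 63 under the other log-ratio form, 21 without Scrublet removal, 18 with at least 50 UMIs per sum, 35 with DESeq2 and at most 8 under each other alternative with the pool as a block. The 24 tumour genes named by rule kept their side in both classes under each alternative run for them. These were other scaling, the mixture caller and no Scrublet removal, and for CD8-like cells also leaving out cluster 6 and equal cluster weights. Other cell filters, other Leiden resolutions and the other log-ratio form were not run for these genes. Of the 61 called CD8-like genes named here, 49 kept their direction within RNA deciles, 53 within clusters, 39 within cluster and RNA tercile and 59 with L-Pha per hashtag UMI. Of 36 Treg-like genes 30 and 31 did within RNA deciles and per hashtag UMI, and of 27 CD4 conventional-like genes 22 did in either. The L-Pha test pairs the sums of each pool through the block, and no pairing was possible between tumours. Depth limits low transcripts such as Mgat5, with 118 and 156 UMIs in CD8-like cells of B16-Ova and MC38-Ova. Leaving out proliferation clusters changed no class, because none of the 4 holds such a cluster, and Treg-like cells, being 1 cluster, gave nothing within clusters or with clusters weighted equally. Each pool alone gives values but no test. For the changes below the cause was not tested.

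Barcodes given to B16-Ova and MC38-Ova were 33.7% and 42.8% by the mixture, 30.6% and 36.9% by the ratio of hashtags, and 38.0% and 24.4% by the other log-ratio form. Under that form the share differences were 11.4 points for Treg-like, −6.82 for CD4 conventional-like and 3.18 for NK/NKT-like cells. Leiden resolution 0.5 gave 2.26 points for CD8-like and 0.198 for NK/NKT-like cells, and resolution 2 gave −2.24 for Treg-like cells. The other differences stayed within their intervals.

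L-Pha of Treg-like over CD4 conventional-like cells was 2.80 in B16-Ova and 2.13 in MC38-Ova at resolution 0.5, and in MC38-Ova 2.77 at resolution 2, 2.84 without Scrublet removal and 2.25 under the other log-ratio form. Per hashtag UMI it was 2.07 and 1.64, with CD8-like ratios of 2.36 and 1.29. Per RNA UMI it was 1.85 and 1.51, with CD8-like ratios of 1.19 and 0.877 and an NK/NKT-like ratio of 0.994 in B16-Ova. The top over bottom PD-1 quartile ratio in CD8-like cells of B16-Ova and MC38-Ova was 1.59 and 1.16 per hashtag UMI, 1.09 and 1.28 per RNA UMI and 1.55 and 1.53 within RNA deciles. The Tim-3 ratio was 1.60 and 1.11, 1.21 and 1.06, and 1.55 and 1.32 in that order. MC38-Ova over B16-Ova, per RNA UMI, was 0.739 for L-Pha, 1.16 for PD-1 and 1.19 for Tim-3 on CD8-like cells, and 0.954 for PD-1 and 0.998 for Tim-3 on Treg-like cells. Per hashtag UMI, PD-1 on CD8-like cells was 0.930, and L-Pha was 0.962 on CD4 conventional-like and 0.969 on NK/NKT-like cells, for which it was 1.08 per RNA UMI.

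Counts of genes called between L-Pha groups moved most. For CD8-like cells (698) they were 306 with terciles, 235 at the median, 93 within RNA deciles, 101 within clusters, 43 within cluster and RNA tercile, 314 without Scrublet removal, 55 under the other log-ratio form, 1103 without the low-count filter, 272 with at least 50 UMIs per sum and 114 with DESeq2. For Treg-like cells (507) they were 219 with terciles, 265 at the median, 281 within RNA deciles, 317 within cluster and RNA tercile, 312 with DESeq2's size factors and 58 with DESeq2. For CD4 conventional-like cells (354) they were 53 within RNA deciles, 66 within clusters, 9 within cluster and RNA tercile, 13 per hashtag UMI, 48 under the other log-ratio form, 182 with at least 50 UMIs per sum and 27 with DESeq2. Without the pool as a block, edgeR called 0 genes in each class, with 986, 542 and 700 below an unadjusted p of 0.05. Other counts stayed within 1.5-fold. DESeq2's own filter gives fewer genes an adjusted p.

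Within RNA deciles the direction turned in CD8-like cells for Gzmc (−0.17), Ccl9 (−0.50), Ifit3 (0.10), Irf8 (−0.0324), Rpn1 (−0.19), Gnpnat1 (−0.28), Tpi1 (−0.11), Tnfrsf4 (−0.0752), Idi1 (−0.0596), Gzmb (−0.16), Ccl5 (0.49) and Ccl3 (−1.06). It turned in Treg-like cells for Rrm2 (−0.00921), Tk1 (−0.38), Pclaf (−0.72), Mcm2 (−0.53), Mcm5 (−0.44) and Foxp3 (0.0874), and in CD4 conventional-like cells for Il13 (−0.45), Igfbp7 (−0.28), Ube2c (−0.70), Il2 (−1.30) and Tcf7 (0.0429). Within clusters it turned in CD8-like cells for Gzmm (0.13), Rgs16 (−0.10), Entpd1 (−0.25), Gnpnat1 (−0.0168), Havcr2 (−0.33), Ighm (0.0537), Itgax (0.10) and Ccl3 (−0.31), and in CD4 conventional-like cells for Il13 (−0.22) and Il2 (−1.58).

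Within cluster and RNA tercile it turned in CD8-like cells for Gzmf (−0.48), Gzmc (−0.52), Ccl9 (−0.62), Gldc (−0.00447), Mt2 (−0.16), Gzmm (0.0889), Klf3 (0.0684), Tcf7 (0.13), Ifit3 (0.16), Irf8 (−0.19), Rpn1 (−0.14), Gnpnat1 (−0.28), Tpi1 (−0.10), Idi1 (−0.0794), Cyp51 (−0.0554), Havcr2 (−0.22), Gzmb (−0.21), Ighm (0.0962), Itgax (0.0121), Cdkn2a (−0.24), Ccl5 (0.13) and Ccl3 (−0.86). In CD4 conventional-like cells it turned for Igfbp7 (−0.78), Ube2c (−0.0283), Il2 (−2.07) and Lag3 (−0.0926).

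With L-Pha per hashtag UMI it turned in CD8-like cells for Tnfrsf4 (−0.35) and Ccl3 (−0.73), in Treg-like cells for Ccl3 (−0.0945), Gzmk (−0.26), Cd8a (−0.83), Ccl4 (−0.69) and Cd8b1 (−1.03), and in CD4 conventional-like cells for Il13 (−1.40), Csf2 (−0.38), Ube2c (−0.36), Dtx1 (0.45) and Ifng (−1.57). Il13 also turned under the other log-ratio form (−0.17), and Xcl1 in CD8-like cells without cluster 6 (0.77). Between tumours in CD8-like cells, weighting clusters equally turned the naive and memory median (−0.12), Pdcd1 (1.14), Tcf7 (0.734), Cd4 (0.961) and Xist (0.980), and leaving out cluster 6 turned the glycolysis median (−0.15), Ccl4 (0.657), Gzmb (0.821), Havcr2 (0.447) and Cd8a (0.783).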

Other observations

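Clusters outside the 4 classes spanned a wide range of L-Pha. The resting-like cluster 5, led by Ccr7 and Dapl1, was low, with medians of 240.0 in B16-Ova and 248 in MC38-Ova. Cluster 8, led by the interferon-induced genes Ifit3 and Isg15, had medians of 285.5 and 319, with Isg15 at 2308 and 2093 CPM. Cluster 11, led by Tmem176b, Ramp1 and Il7r, had medians of 353.5 and 365.5. It carried Zbtb16 at 106 and 152 CPM and Il17a at 28.7 and 75.9 CPM, and Mgat5 at 72.6 CPM (43 UMIs) and 69.8 CPM (57 UMIs). The proliferating cluster 9, led by Pclaf, Stmn1 and Top2a with Mki67 at 496 and 522 CPM, had medians of 1004 and 513 and 16497.5 and 12175 RNA UMIs per cell.

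L-Pha medians of other clusters without a class name follow. Cluster 14, led by Cd74 and Lyz2 but with Cd3e at 729.9 CPM in B16-Ova and 456 CPM in MC38-Ova, had medians of 1512.5 in B16-Ova (18 cells) and 1440.0 in MC38-Ova (74 cells). The stroma-like cluster 15, led by Col3a1, had 2183 in MC38-Ova (65 cells). Melanoma-like cells had 892 with the B16-Ova hashtag (57271.5 RNA UMIs per cell) and 334.5 with the MC38-Ova hashtag (7562.5 RNA UMIs per cell). Cluster 12, led by heat-shock genes, held 130 B16-Ova and 13 MC38-Ova cells, with Hspa1a at 4529 and 3623 CPM. In cluster 16, 1 cell held 2366 of 2367 haemoglobin UMIs of B16-Ova.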
